A study of Homo sapiens and Rattus norvegicus with 100 samples.

How the data were processed

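RNA from the orbitofrontal cortex of 62 human and 38 rat samples was sequenced. Per the labels' protocols, human RNA was isolated with a ToTally RNA kit and libraries were made with the TruSeq RNA kit v2. Rat RNA was isolated with TRIzol, and polyadenylated transcripts were copied into full-length cDNA and amplified with the SMART-Seq v4 kit. Neither protocol names a strand-specific step or molecular identifiers, so reads from overlapping genes on opposite strands cannot be told apart. PCR copies are not independent molecules, so the number of reads bounds counting error only.

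The human table was deposited as log10 of FPKM plus 1 (fragments per kilobase of transcript per-million fragments) for 56986 transcript rows, with a class code and coordinates per row; the log scale was read from the values, which reach back to a floor of 0.01 FPKM. The rat table was deposited as raw read counts for 34322 gene symbols. The submitters' processing notes name TopHat2 2.0.8b, Cufflinks 2.1.1 and STAR, and the builds GRCh37 and mRatBN7.2, without saying which step each served. The counting program and the annotation are not given in the sources used here. A class code of j marks, in Cufflinks output, an assembled transcript that shares a splice junction with a known one, and 24183 human rows carried it; 32738 rows had class 0. A further column of whole numbers per transcript was not used here because its meaning is not stated. No other column of per-sample values was left out.

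Groups were taken from the labels alone. Replicate numbers were given in accession order and pair no samples. The human design had been written for FPKM values; since the file holds their log10, the values were turned back to FPKM and summed per gene, giving 20108 gene names after 65 rows of sex-linked genes had been left out of all human tests. Genes with at least 0.5 FPKM in at least 28 libraries were kept (14029), and log2(FPKM + 0.5) was tested with limma 3.58.1 in R 4.3.3, with trended empirical Bayes moderation. Human fold changes are on this log2(FPKM + 0.5) scale, which understates changes of genes near the pseudocount. Single transcript rows were tested on the deposited log10 scale.

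Rat counts were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) with TMM scaling and filterByExpr over the 4 groups in a single model, which kept 18398 genes. The contrasts were SHISA7 minus RFP within heroin and within saline, heroin minus saline within RFP and within SHISA7, and the difference between the first 2. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes of a contrast, with 0.05 as the threshold. CPM values are counts-per-million of the TMM-scaled library size, and log2 CPM uses a prior count of 2. Single values were also tested by permuting the group labels, with exact enumeration or 100000 resamples. The 95% intervals of Shisa7 come from the edgeR coefficient and its standard error.

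Before the data were examined, 27 gene lists were fixed: markers of cell types, glutamate, GABA, monoamine and opioid signalling, ion channels, synaptic vesicles, activity and stress responses, immune genes and metabolic genes. A list with at least 3 tested genes was tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, which tests whether a list moves on balance 1 way without comparing it with other genes. Rat symbols were matched to the lists without regard to case. The named genes followed a rule fixed at the same time: SHISA7; the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with a mean of at least 1 FPKM or 1 log2 CPM and a gene symbol; and up to 4 called members of each list by p. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were given as values that did not pass. LOC102552552, the neighbours of SHISA7, Fos, and the genes named in the closing section outside this rule were chosen after their values were seen.

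The classifier was an L2-penalised logistic regression in scikit-learn 1.9.0 (NumPy 2.4.6, pandas 2.3.3) on the 200 genes with the smallest p in each training fold, in 5 folds repeated 10 times and compared with 100 permutations of the labels. Correlations of fold changes across genes were compared with 100 regroupings of the libraries, and human and rat genes were matched by symbol without regard to case.

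The gene tests between 2 groups, camera in the human data and the classifier were run on simulated data first. The interaction, the rat list tests, fry, camera with an estimated correlation and the permutation tests were not. With known changes put into counts drawn from the rat means, edgeR found 22.4%, 92.5% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale between SHISA7 and RFP in heroin, over 18155 genes. In saline these shares were 8.96%, 41.8% and 100%, between heroin and saline with RFP 7.46%, 59.7% and 100%, and with SHISA7 4.48%, 61.2% and 100%. In simulated human values limma found 44.8%, 83.6% and 100% of changes of 0.25, 0.5 and 1 over 14029 genes, and camera found the shifted list and 0 of the 24 others. Those values were drawn independently for each gene. They therefore do not show how often camera with its preset correlation calls lists of correlated genes falsely. No 2 libraries held identical values among 703 rat and 1891 human pairs.

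Alternatives fixed before the data were examined covered the pseudocount, filters, scaling, covariates, surrogate variables (sva 3.50.0), robust moderation with weights, DESeq2 1.42.0, limma-voom with sample weights, the form of the title number as a covariate or stratum, models with only the 2 groups compared, leaving out each saline RFP library, and other list tests. Leaving out the 8 libraries with other titles, leaving out each library of the other 3 rat groups, leaving out each rat library in the list tests, testing single transcript rows and leaving out single SHISA7 rows were added after the data had been seen. Adjusted p-values that DESeq2 set to missing were kept as missing.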

Results

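RNA was sequenced from the orbitofrontal cortex, a frontal brain region that weighs expected outcomes, of humans and rats. The human part held 62 libraries, 34 labelled heroin and 28 labelled control. The rat part held 38 libraries with a drug label, heroin or saline, and a second label, RFP or SHISA7: 13 heroin RFP, 13 heroin SHISA7, 5 saline RFP and 7 saline SHISA7. The labels do not say what was done under the second label. The title of the series names Shisa7 as the gene carried over from the human to the rat part; it encodes a membrane protein that associates with AMPA-type glutamate receptors and with GABA-A receptors. The labels do not say that the libraries came from separate donors or animals, so p-values measure only the spread between these libraries, which may be technical.

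Rat total counts ranged from 17.5 to 33.6 M per library. Their means were 22.3 ± 2.28 M (SD, n = 13) in heroin RFP, 25.6 ± 3.53 M (SD, n = 13) in heroin SHISA7, 23.6 ± 1.25 M (SD, n = 5) in saline RFP and 23.2 ± 1.69 M (SD, n = 7) in saline SHISA7. At these depths 1 read stood for 0.0298 to 0.0570 counts-per-million (CPM), and Shisa7 was covered by 183 to 2225 reads per library. The human values were deposited as log10 of FPKM, so the depth of the human libraries is unknown. The number of human transcript rows above the floor of 0.01 FPKM was 38176 ± 1699 (SD, n = 34) in heroin and 39288 ± 1259 (SD, n = 28) in control, a difference of −1112 rows (permutation p = 0.00573).

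The sample numbers in the rat titles took 3 forms: a plain pair of numbers, a pair with a suffix, and other numbers. All 5 saline RFP libraries had suffixed pairs and all 7 saline SHISA7 libraries had plain pairs, so in saline the title form and the second label cannot be told apart. Heroin RFP held 7 plain, 4 suffixed and 2 other titles, and heroin SHISA7 held 2, 5 and 6. The title form took 0.723 of the variance of the second principal component (13.9% of all variance), against 0.330 for the 4 groups. The 8 libraries with other titles fell into 2 sets on the first component: heroin SHISA7 replicates 2, 3, 10 and 12 at −66.5 to −46.3, and replicates 5 and 7 of both heroin groups at 109 to 148. Heroin SHISA7 replicate 11, with a suffixed pair, lay at −48.4, within the range of the former set. The sets were read from the expression values. Titles follow them in part: heroin SHISA7 replicates 2, 10 and 12 bear a suffix after a single number, while the rest of the 8 are single numbers alone. With the title form beside the 4 groups in edgeR, 5877 of 18398 genes passed for the form. The labels do not say what the forms mark.

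**Figure D1:**
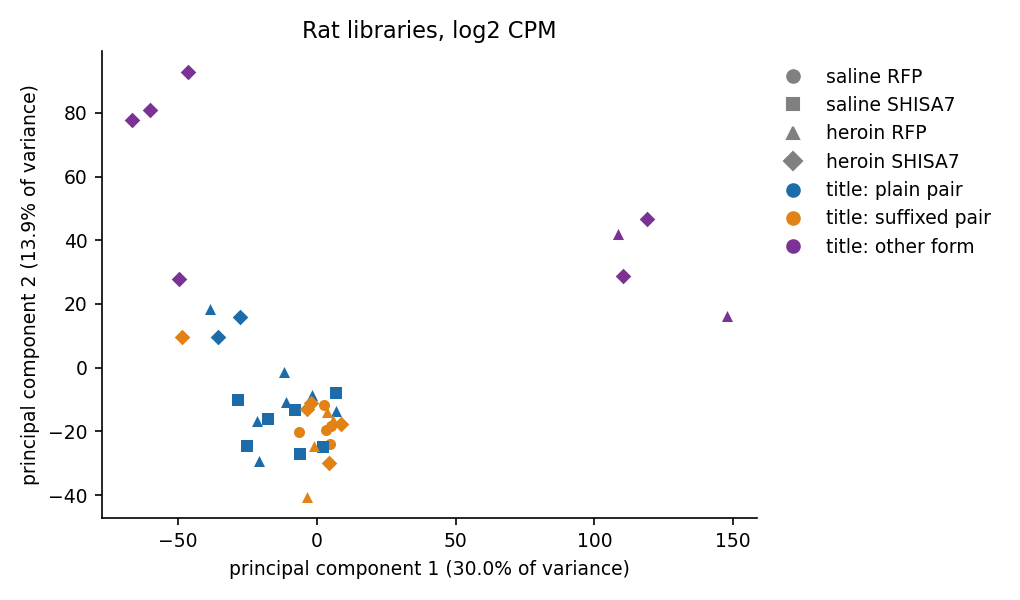
First and second principal components of log2 CPM for the 38 rat libraries, with the marker shape for the group and the colour for the form of the sample number in the title. Libraries with other titles lie in 2 sets at opposite ends of the first component, with heroin SHISA7 replicate 11, a suffixed pair, at −48.4 beside the lower set. The title form took 0.723 of the variance of the second component.

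The first comparison asked which transcripts differed in the orbitofrontal cortex of the human heroin group. SHISA7 was lower in heroin, at 4.61 ± 2.45 FPKM (SD, n = 34) against 12.3 ± 4.50 FPKM (SD, n = 28) in control. The log2 difference was −1.45 (SE 0.199; limma, adjusted p = 1.88e-06), and all 34 heroin libraries lay below the control median. The permutation test gave p = 1e-05, the smallest it can give, and SHISA7 alone separated the groups with an area under the ROC curve of 0.913. The first listed row of SHISA7 has the coordinates 55925364 to 55964269 on chromosome 19 in the file, and those of its other rows were not read. GRCh37 is the human build that the submitters' notes name.

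The difference in SHISA7 lay in 1 of its 3 transcript rows. Row P12080 carries class code j, which Cufflinks gives to an assembled transcript that shares a splice junction with a known one. P12080 was at 2.27 ± 1.65 FPKM (SD, n = 34) in heroin and 9.82 ± 4.12 FPKM (SD, n = 28) in control, a log10 difference of −0.542 (SE 0.0561; limma, adjusted p = 1.01e-09) and the smallest p of the 28834 rows tested. Row P12079, of class 0, was at 1.5 FPKM in heroin and 1.49 FPKM in control (adjusted p = 0.999). Row P12078, also of class j, was at 0.845 and 1.00 FPKM (adjusted p = 0.826). Without P12080 the log2 difference of SHISA7 was −0.13 (adjusted p = 0.835), and with the class 0 row alone it was −0.01 (adjusted p = 0.992). No tested row of the neighbouring genes ISOC2, UBE2S and RPL28 passed.

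**Figure D2:**
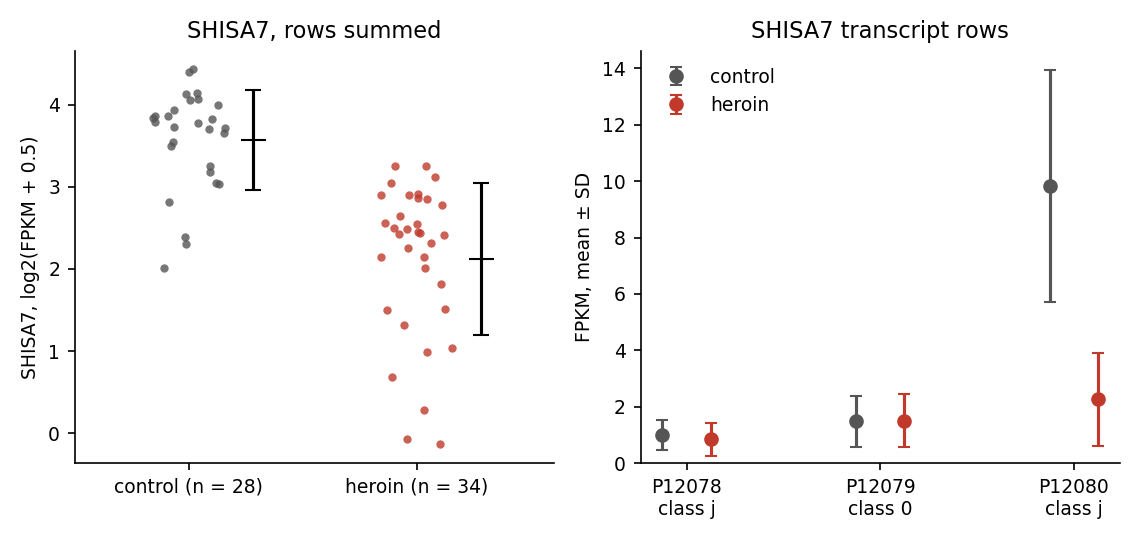
Left, SHISA7 as log2(FPKM + 0.5) in each human library with the mean and SD; right, mean and SD of FPKM for each SHISA7 transcript row in the control (n = 28) and heroin (n = 34) groups. Row P12080 had a mean of 2.27 FPKM in heroin and 9.82 FPKM in control, while P12079 had 1.5 and 1.49 FPKM.

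Of 14029 human genes tested, 110 passed in limma, 33 higher and 77 lower in heroin, and 1730 had an unadjusted p under 0.05. The lower genes with the largest differences were genes of short RNAs. Many libraries of both groups lay at the floor of 0.01 FPKM for these genes. For MIR770 these were 17 of 34 heroin and 6 of 28 control libraries, for RNU6ATAC 16 and 7, for MIR1234 14 and 8, and for SNORA67 5 and 2. For MIR663, which rose, they were 7 and 4. Whether reads on such genes come from the mature short RNAs was not tested. MIR5047 had a log2 difference of −3.78, MIR1234 of −3.76, MIR770 of −3.74, MIR1307 of −2.95 and MIR3936 of −2.85, all named as microRNA genes. SNORA67, a small nucleolar RNA that guides pseudouridylation, had the smallest p: 0.610 ± 0.589 FPKM (SD, n = 34) in heroin against 13.8 ± 11.8 FPKM (SD, n = 28) in control, a log2 difference of −3.10 (SE 0.325, adjusted p = 9.15e-10). SNORA61 (−2.62) and RNU6ATAC (−2.81), a small nuclear RNA of the minor spliceosome, fell too. MIR663 went the other way, at 50.2 ± 41.4 FPKM (SD, n = 34) against 2.22 ± 1.99 FPKM (SD, n = 28), a log2 difference of 3.33 (SE 0.559, adjusted p = 1.44e-04) with 27 of 34 heroin libraries above the control median. Short RNA genes made up 10 of the 110 called genes, 8 of them lower: 29.4% of the 34 tested passed, against 0.715% of the other 13995 genes (Fisher's exact test, p = 6.49e-14).

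Smaller rises were seen among protein-coding genes. ELK1, a transcription factor that acts on serum response elements, was at 27.0 ± 5.90 FPKM in heroin and 19.5 ± 4.37 FPKM in control (log2 difference 0.46, SE 0.0745, adjusted p = 9.09e-05) and lay above the control median in all 34 heroin libraries. JUN, a component of the AP-1 transcription factor, rose by 0.44 (SE 0.0987, adjusted p = 0.00977), and NPY1R, a receptor of neuropeptide Y, by 0.75 (SE 0.167, adjusted p = 0.00977). The calcium-activated channel family member ANO3 (0.36), the ubiquitin ligase NEURL1B (0.35), the ciliary transcription factor RFX3 (0.32), the presynaptic scaffold RIMS4 (0.32), the transcription factor NFIB (0.30) and SKIL (0.30), a repressor of TGF-beta signalling, rose as well. The postsynaptic scaffold SHANK2 rose by 0.24 (adjusted p = 0.0470). ABCB1, the drug efflux pump of the blood-brain barrier, was lower, with a log2 difference of −0.44 (SE 0.107, adjusted p = 0.0212; 3.46 against 4.65 FPKM), and so was the pseudogene HSP90AA6P (−0.80, adjusted p = 0.00265), whose reads cannot be separated with certainty from those of its parent gene family. The split of 33 higher and 77 lower genes moved to 76 and 65 with quantile normalization and to 45 and 60 with median-of-ratios scaling.

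Of 25 gene lists tested in the human data, 11 passed in camera with its preset correlation and none with an estimated one. Markers of microglia, the resident immune cells of the brain, were lower as a group: 16 of 16 were lower, with a mean log2 difference of −0.58 (adjusted p = 6.27e-10; adjusted p = 0.437 with an estimated correlation). None of them passed over all genes and 10 passed adjusted over the list alone. Oligodendrocyte markers (14 of 15 lower, mean −0.27, adjusted p = 3.65e-04), interferon-induced genes (27 of 29 lower, mean −0.16, adjusted p = 1.92e-04) and vascular markers (13 of 16 lower, mean −0.15, adjusted p = 0.00285) were lower with the preset correlation, each at an adjusted p = 0.640 with an estimated one. ABCB1 was the vascular member past the test over all genes, and 6 passed adjusted over the list alone. Markers of inhibitory neurons were lower too (15 of 20, mean −0.13, adjusted p = 0.0336; adjusted p = 0.735 with an estimated correlation).

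Lists of glutamate receptors were higher in the human heroin group. All 7 metabotropic glutamate receptor genes were higher, with a mean of 0.17 (adjusted p = 6.96e-05; adjusted p = 0.0532 with an estimated correlation), 0 passed over all genes and 3 adjusted over the list alone. Of 17 AMPA, NMDA, kainate and delta receptor subunit genes 15 were higher (mean 0.07, adjusted p = 0.00242; adjusted p = 0.506 with an estimated correlation). Of 27 genes of AMPA receptor auxiliary and scaffold proteins 17 were higher (mean 0.06, adjusted p = 0.00248; adjusted p = 0.640 with an estimated correlation), with SHANK2 past the test and 3 adjusted over the list alone. Immediate early genes, which neurons switch on with activity, were higher in 23 of 33 (mean 0.09, adjusted p = 0.00706; adjusted p = 0.640 with an estimated correlation), with JUN past the test. Heat shock genes (14 of 21 higher) and hypoxia genes (13 of 22 higher) each had an adjusted p = 0.0199, and adjusted p of 0.654 and 0.640 with an estimated correlation. The opioid system list, with the opioid receptors and their peptide precursors, did not pass (adjusted p = 0.938); 2 of its 7 genes were higher, with a mean of −0.06, although the test ranked the list as higher.

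The title of the series mentions machine learning on the human transcriptome, and a penalised logistic regression was trained to tell heroin from control libraries. On libraries left out of training, the 200 genes with the smallest p per fold gave an area under the ROC curve of 0.954 (SD 0.0197 over 10 repeats of 5 folds). With permuted labels the mean was 0.480 and the highest 0.669, so p = 0.0099, the smallest that 100 permutations can give. SHISA7 was among the chosen genes in 50 of 50 folds. Without SHISA7 and the short RNA genes the area was 0.903.

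In the rat, Shisa7 itself was read first, because the second label carries its name. Shisa7 was at 41.7 ± 16.3 CPM (SD, n = 13) in heroin SHISA7 and 26.1 ± 5.73 CPM (SD, n = 13) in heroin RFP, a log2 difference of 0.68 (SE 0.168; edgeR, adjusted p = 0.0202; 95% interval 0.35 to 1.01), with 10 of 13 SHISA7 libraries above the RFP median. The permutation test gave p = 0.00757. In saline, Shisa7 was at 33.9 ± 7.52 CPM (SD, n = 7) with SHISA7 and 27.4 ± 1.11 CPM (SD, n = 5) with RFP; the log2 difference of 0.31 (SE 0.252, adjusted p = 1.00, exact permutation p = 0.0682) did not pass and its 95% interval ran from −0.18 to 0.80. The heroin and saline differences of Shisa7 differed by 0.37 (interval −0.22 to 0.96, unadjusted edgeR p = 0.229), which did not pass. With RFP, Shisa7 differed between heroin and saline by −0.07 (interval −0.51 to 0.37, exact permutation p = 0.584), and with SHISA7 by 0.30 (SE 0.202, exact permutation p = 0.418). Within heroin, the log2 difference of Shisa7 was 0.42 among suffixed titles (adjusted p = 1.00), 0.77 among plain pairs (adjusted p = 0.402) and 1.39 among other titles (adjusted p = 0.283). Among other titles, Shisa7 was at 44.2 to 68.0 CPM in SHISA7 replicates 2, 3, 10 and 12, a set without an RFP library. In the other set it was at 18.1 and 19.4 CPM in SHISA7 replicates 5 and 7, against 17.9 and 13.3 CPM in RFP replicates 5 and 7. The 1.39 therefore compares in part unlike sets. Without the 8 libraries with other titles it was 0.53 (SE 0.133, unadjusted p = 4.00e-04, adjusted p = 0.817). The counts of all reads on Shisa7 do not say whether they come from the rat's own gene.

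**Figure D3:**
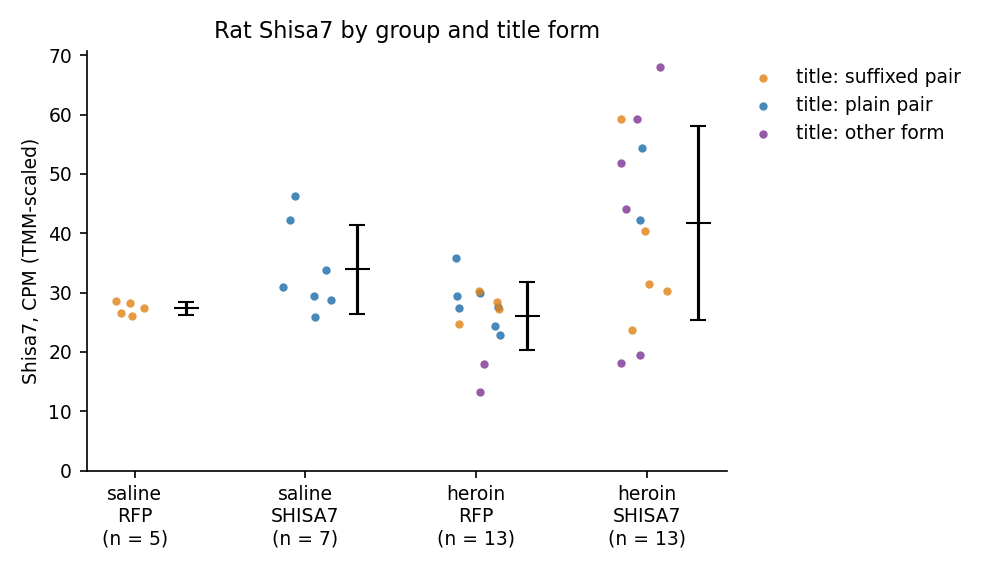
Shisa7 in CPM in each rat library by group, coloured by the form of the sample number in the title, with the mean and SD of each group beside the points. Heroin SHISA7 had a mean of 41.7 CPM (n = 13) and heroin RFP of 26.1 CPM (n = 13).

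Among heroin-labelled rats, 785 of 18398 genes differed between SHISA7 and RFP in edgeR, 751 higher and 34 lower with SHISA7. Among the higher ones Cnih2, an auxiliary subunit that carries AMPA receptors to the membrane, was at 26.8 ± 40.04 CPM (SD, n = 13) against 4.21 ± 1.75 CPM (SD, n = 13), a log2 difference of 2.67 (SE 0.512, adjusted p = 0.0150). Rn45s, the ribosomal RNA precursor, had the largest difference among the named genes, at 622 ± 1067 CPM (SD, n = 13) against 65.7 ± 53.1 CPM (SD, n = 13), a log2 difference of 3.25 (SE 0.632, adjusted p = 0.0150). The secreted factor C1qtnf4 (2.29), the transcription factor subunit Taf10 (2.27), Camk2n1 (2.16), an inhibitor of CaM kinase II, the semaphorin Sema6b (2.12), the AP-1 member Jund (2.03), the activity-induced factor Egr4 (2.02), the kinase Dapk3 (1.98) and the synaptic adhesion protein Lrfn1 (1.97) rose too.

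Among the 34 lower genes, Lgals3, a galectin of activated microglia and macrophages, was at 6.44 ± 4.77 CPM (SD, n = 13) with SHISA7 and 19.5 ± 15.0 CPM (SD, n = 13) with RFP, a log2 difference of −1.60 (SE 0.426, adjusted p = 0.0259), and lay below the RFP median in 13 of 13 libraries. Gpnmb, a glycoprotein of the same cells (−1.38), the actin-capping protein Capg (−0.90), the thromboxane synthase Tbxas1 (−0.89), the interferon gamma receptor Ifngr1 (−0.31), the synaptotagmin Syt10 (−0.76), endothelin Edn1 (−0.66), the endothelial protein Nostrin (−0.54), Tspyl4 (−0.48) and Zfp105 (−0.39) fell as well. When the 8 libraries with other titles were left out, Lgals3 was at −1.37, Gpnmb at −1.41, Capg at −0.82, Tbxas1 at −0.80, Nostrin at −0.49, Edn1 at −0.52, Tspyl4 at −0.38 and Ifngr1 at −0.19, each at an adjusted p = 0.817, with Syt10 at −0.45 and Zfp105 at −0.18, which did not pass either.

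The higher genes moved with part of the libraries with other titles. Across the 751 genes the median log2 difference was 0.86 with all libraries and 0.26 without those 8, with 714 of 748 still above 0. Within heroin SHISA7, libraries with other titles had these genes higher than the rest by a median of 0.91, and within heroin RFP by −0.01. That rise lay in replicates 2, 3, 10 and 12, which were above heroin SHISA7 libraries with pairs of numbers by a median of 1.40, while replicates 5 and 7 differed from these by −0.01. Without those 4 libraries the median for SHISA7 minus RFP in mean log2 CPM was 0.22, against 0.65 with all libraries on that scale, and 0.24 within the other set of other titles (2 against 2 libraries). The sets were split by the sign of the first component of the same values, and the 751 genes were called with these libraries. The gap between the sets thus describes these libraries and is no test. Rn45s was at 3098, 2587 and 1508 CPM in heroin SHISA7 replicates 10, 3 and 2, at 107 to 267 CPM in the other 5 libraries with other titles, 46.8 ± 11.2 CPM (SD, n = 16) with plain pairs and 51.5 ± 8.78 CPM (SD, n = 14) with suffixed pairs. With all 8 left out, edgeR called 0 genes and 1086 had an unadjusted p under 0.05. Rn45s then stood at −0.02, Cnih2 at 0.48, C1qtnf4 at 0.01, Taf10 at 0.05, Camk2n1 at −0.05, Sema6b at 0.02, Jund at 0.51 and Egr4 at 0.21. Leaving out any of heroin SHISA7 replicates 2, 3 and 10, all with other titles, also left 0 genes in edgeR, with 2428, 2498 and 2351 at an unadjusted p under 0.05. Over all libraries limma-voom called 0 genes, with 2706 at an unadjusted p under 0.05, and DESeq2 1080.

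**Figure D4:**
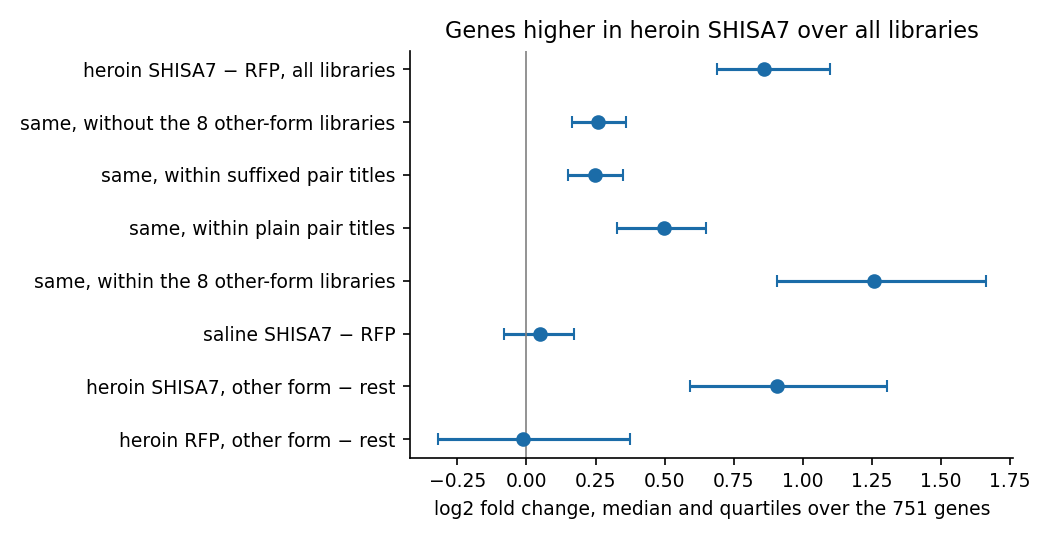
Median and quartiles of the log2 difference over the 751 genes called higher with SHISA7 in heroin, for all libraries, for subsets by title form, for saline, and for other titles against the rest within each heroin group. The median is 0.86 with all libraries, 0.26 without the 8 libraries with other titles, 0.05 in saline and 0.91 between other titles and the rest of heroin SHISA7.

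Of 26 lists tested between SHISA7 and RFP in heroin, 15 passed in camera with the preset correlation and none with an estimated one. Potassium and sodium channel genes were higher in 26 of 28 (mean 0.54, adjusted p = 4.46e-07; adjusted p = 0.317 with an estimated correlation), 7 past the test over all genes and 15 adjusted over the list alone. Hcn2, a pacemaker channel, rose by 2.85 and Kcnc1 by 0.73. Genes of AMPA receptor auxiliary and scaffold proteins were higher in 22 of 27 (mean 0.44, adjusted p = 4.67e-04; adjusted p = 0.254 with an estimated correlation), 4 over all genes and 11 over the list alone: Cnih2, Dlg3 (0.97), Homer1 (0.93) and Shank3 (0.64). Of 18 AMPA, NMDA, kainate and delta receptor subunit genes 13 were higher (adjusted p = 0.0194; adjusted p = 0.476 with an estimated correlation), with Grik5 (1.62) and Grin2c (1.26) past the test. Of 23 genes of GABA receptors and chloride transport 16 were higher (adjusted p = 0.00948; adjusted p = 0.453 with an estimated correlation), and the chloride transporters Slc12a5 (0.85) and Slc12a2 (0.72), Gabbr1 (0.58) and the inhibitory-synapse protein Iqsec3 (0.59) rose. Over the remaining 30 libraries, without other titles, Hcn2 was at 0.26, Homer1 at 0.36, Grik5 at 0.35, Slc12a5 at 0.02 and Slc12a2 at 0.62, none past the test. With the preset correlation the GABA list (mean from 0.25 to 0.05, adjusted p = 0.872) and the receptor subunit list (0.35 to 0.11, adjusted p = 0.153) then no longer passed. The channels (0.54 to 0.12, adjusted p = 0.00348) and the auxiliary proteins (0.44 to 0.15, adjusted p = 0.0270) did, though at an adjusted p = 0.357 each with an estimated correlation. Leaving out single libraries also ended calls with the preset correlation. The subunit list did not pass without heroin RFP replicate 5 (adjusted p = 0.0822) or 7 (0.185). The GABA list did not pass without replicate 7 (0.0794).

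Markers of several cell types moved alongside. Excitatory neuron markers were higher in 12 of 15 (mean 0.45, adjusted p = 0.00181; adjusted p = 0.254 with an estimated correlation), with the vesicular glutamate transporter Slc17a7 (1.27; 588 ± 510.99 against 245 ± 75.2 CPM, n = 13 each), Itpka (1.15), Tbr1 (0.92) and Neurod2 (0.80) past the test. Markers of oligodendrocyte precursors were higher in 8 of 9 (mean 0.78, adjusted p = 0.00918; adjusted p = 0.317 with an estimated correlation), with C1ql1 (2.45), Olig1 (1.35) and Sox10 (1.20) past the test. Synaptic vesicle genes were higher in 24 of 32 (adjusted p = 0.0406; adjusted p = 0.476 with an estimated correlation), with Syn2 (0.99), Bsn (0.77) and Syt7 (0.70), and immediate early genes in 22 of 34 (adjusted p = 0.00948; adjusted p = 0.317 with an estimated correlation), with Egr4, Jund, Klf2 (1.79) and Homer1. The vesicle list no longer passed without any 1 of heroin RFP replicates 2, 5 and 7 or heroin SHISA7 replicates 1, 4, 6 and 8 to 12 (adjusted p 0.0506 to 0.170). Nor did the immediate early list without heroin RFP replicate 12 (0.1252). Single members of lists that did not pass rose as well: the dopamine receptor Drd2 (1.87), the adrenergic receptors Adrb1 (3.06) and Adra2c (1.68), the chaperone Dnaja4 (0.98), Vegfa (0.87) and Timp2 (0.96). Drd2 was at 1.55 ± 1.84 CPM with SHISA7 and 0.418 ± 0.200 CPM with RFP (n = 13 each). Slc17a7 was at 1080 to 1446 CPM in heroin SHISA7 replicates 2, 3, 10 and 12, at 141 to 227 CPM in the other 4 libraries with other titles, 268 ± 72.5 CPM (SD, n = 16) with plain pairs and 241 ± 72.6 CPM (SD, n = 14) with suffixed pairs. With the 8 left out, Slc17a7 was at 0.16, Neurod2 at 0.20, Tbr1 at 0.31, Itpka at 0.21, Olig1 at 0.75, Sox10 at 0.78, Drd2 at 1.5 and Adrb1 at −0.29. The list means went from 0.45 to 0.14 for excitatory neurons and from 0.78 to 0.39 for precursors. Their adjusted p in camera were 0.0448 and 0.0313 with the preset correlation, and 0.310 and 0.377 with an estimated one. Oligodendrocyte markers, which did not pass over all libraries, went from 0.34 to 0.62 (adjusted p = 7.78e-04, and 0.389 with an estimated correlation). In the libraries' list means of log2 CPM, heroin SHISA7 replicate 13 was at 8.67. Other heroin SHISA7 libraries with pairs were at 6.05 to 6.61, and heroin RFP libraries with pairs at 5.78 to 6.75. The rise thus rested on heroin SHISA7 replicate 13.

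Immune and vascular lists were lower with SHISA7 in heroin. All 26 interferon-induced genes were lower (mean −0.52, adjusted p = 4.46e-07; adjusted p = 0.254 with an estimated correlation), as were 15 of 16 microglia markers (mean −0.42, adjusted p = 1.20e-05; adjusted p = 0.254 with an estimated correlation) and 22 of 25 inflammation genes (mean −0.55, adjusted p = 7.38e-05; adjusted p = 0.247 with an estimated correlation). None of their members passed over all genes or adjusted over the list alone. Without the 8 libraries with other titles the 3 lists stayed lower with the preset correlation, at adjusted p of 1.67e-08, 2.50e-06 and 6.88e-06, and at an adjusted p = 0.310 each with an estimated one. Vascular markers (12 of 15 lower, adjusted p = 0.00918, 2 over the list alone), blood genes (7 of 7, adjusted p = 0.00181), astrocyte markers (13 of 15, adjusted p = 0.0148) and nuclear genes of oxidative phosphorylation (72 of 75, mean −0.13, adjusted p = 1.18e-04) were lower, with adjusted p of 0.254, 0.317, 0.314 and 0.667 with an estimated correlation. Oxidative phosphorylation genes no longer passed without the 8 libraries (mean 0.03, adjusted p = 0.996 with the preset correlation) or without heroin RFP replicate 7 alone (0.129). In the libraries' list means their difference of −0.16 became −0.05 without that library, −0.07 without heroin RFP replicate 5, and −0.10 and −0.26 without heroin SHISA7 replicates 3 and 5.

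Among saline-labelled rats, edgeR called 0 of 18398 genes between SHISA7 and RFP, with 393 at an unadjusted p under 0.05. DESeq2 called 3 and limma-voom 9. In the simulation of this comparison 41.8% of genes changed by 1 on the log2 scale and all of those changed by 2 were found, so differences of the former size could be missed. Immediate early genes stood lower with SHISA7 as a group: 34 of 34 were lower, with a mean of −0.49 (adjusted p = 9.19e-13; adjusted p = 0.010 with an estimated correlation), and 1 passed adjusted over the list alone. In fry the list did not pass (adjusted p = 0.0537), while without the 8 libraries with other titles, none of them saline, the mean was again −0.49. The preset test then gave an adjusted p = 1.75e-11 and the one with an estimated correlation 0.251, as that correlation rose from 0.119 to 0.237. Without saline RFP replicate 5 the latter was 0.0784. Nr4a3, an orphan nuclear receptor induced by activity, was at 4.02 ± 0.793 CPM (SD, n = 7) with SHISA7 and 7.86 ± 0.944 CPM (SD, n = 5) with RFP, a log2 difference of −0.97 that did not pass over all genes (adjusted p = 1.00). Its relative Nr4a2 (−1.28), Ccn1 (−1.59), the prostaglandin D synthase Ptgds (−1.23) and Cd4 (−0.97) did not pass, nor did Atcay (0.45), Aifm3 (0.53), Tmem266 (0.89), Csad (0.43) and MGC95210 (0.42), each at an adjusted p = 1.00.

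The other lists that differed in saline were lower with SHISA7 too. Oligodendrocyte markers were lower in 15 of 15 (mean −0.70, adjusted p = 1.55e-08; adjusted p = 0.407 with an estimated correlation), microglia markers in 15 of 16 (mean −0.46, adjusted p = 2.99e-04; adjusted p = 0.557 with an estimated correlation) and blood genes in 7 of 7 (mean −0.77, adjusted p = 4.67e-05; adjusted p = 0.407 with an estimated correlation). Oxidative phosphorylation genes (71 of 75, mean −0.17) and ribosomal protein genes (72 of 73, mean −0.13) were lower at adjusted p of 1.68e-04 and 0.00172, both at an adjusted p = 0.883 with an estimated correlation. Single libraries carried part of this. On the scale of the libraries' list means, the oligodendrocyte difference went from −0.58 to −0.32 without saline RFP replicate 3 (adjusted p = 0.00227). The microglia difference went from −0.35 to −0.14 without saline RFP replicate 2 (adjusted p = 0.263), to −0.23 without saline SHISA7 replicate 1 and to −0.60 without saline RFP replicate 5. Ribosomal protein genes no longer passed without saline SHISA7 replicate 4 (adjusted p = 0.0564). Interferon-induced genes, which did not pass over all libraries (0.120), were lower with the preset correlation without saline SHISA7 replicate 2 (1.68e-05) or 5 (0.0162) or saline RFP replicate 5 (3.12e-04). So were inflammation genes without SHISA7 replicate 2 (0.0303) or RFP replicate 5 (0.00672). With an estimated correlation, neither interferon-induced nor inflammation genes passed in camera without SHISA7 replicate 2 (adjusted p = 0.362 each). In saline each of these lists moved with the title form as much as with the second label, since the 2 labels coincide there. Across title forms, Fos, the canonical immediate early gene, was at 82.8 ± 38.2 CPM (SD, n = 16) with plain pairs, 163 ± 22.0 CPM (SD, n = 14) with suffixed pairs and 112 ± 45.9 CPM (SD, n = 8) with other titles. Within heroin RFP the mean log2 CPM of the immediate early list was lower with plain pairs (n = 7) than with suffixed pairs (n = 4) by −0.46 (exact permutation p = 0.0121). Within heroin SHISA7 the gap was smaller, with 4.50 ± 0.0533 (SD, n = 2) for plain and 4.69 ± 0.325 (SD, n = 5) for suffixed pairs.

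**Figure D5:**
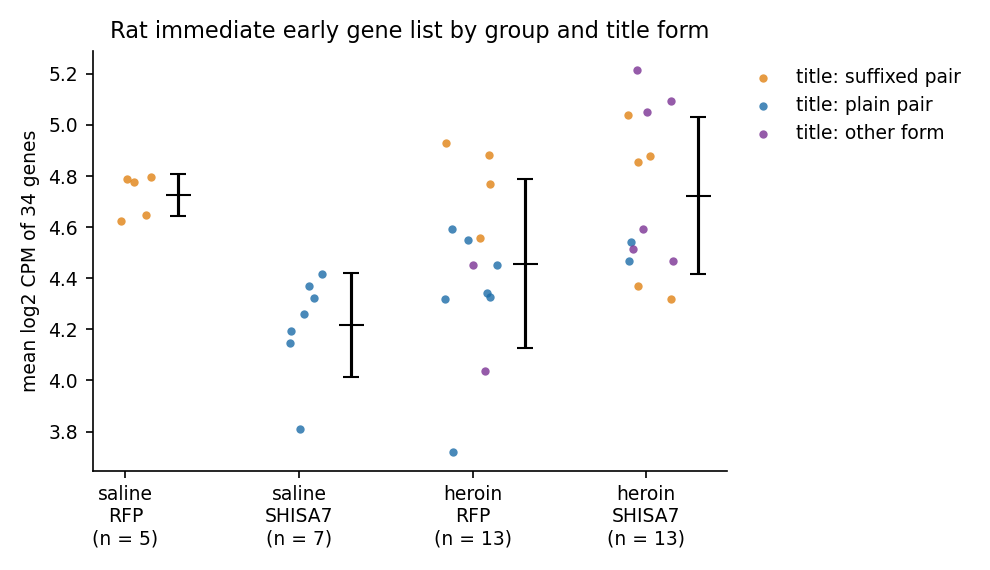
Mean log2 CPM of 34 immediate early genes in each rat library by group, coloured by the form of the sample number in the title, with the mean and SD of each group. In saline the SHISA7 group (4.22 ± 0.204, n = 7, plain pairs) lies below the RFP group (4.73 ± 0.0830, n = 5, suffixed pairs).

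The effect of the heroin label was read first in RFP rats. A single gene, LOC102552552, was lower in heroin (log2 difference −7.25, SE 1.24, adjusted p = 0.0157), and 213 had an unadjusted p under 0.05. Its value rested on saline RFP replicate 1, at 41.2 CPM, with 6.32 CPM in replicate 4; without replicate 1 edgeR called 0 genes, with 207 at an unadjusted p under 0.05. Over all libraries DESeq2 called 0 genes, with 393 at an unadjusted p under 0.05, and limma-voom 3. In the simulation of this comparison 59.7% of genes changed by 1 on the log2 scale were found. The mitochondrial protein Tmem65 (1.26), Rccd1 (0.37), the kinase Stk11 (1.75), Atcay (0.34) and Pnma1 (0.45) were the higher genes with the smallest p, and Cd4 (−0.86), Itgbl1 (−0.98), Adpgk (−0.53), Ormdl1 (−0.56) and the glucocorticoid-induced kinase Sgk1 (−0.63) the lower ones, all at an adjusted p = 1.00. Oligodendrocyte markers were lower in 15 of 15 (mean −0.43, adjusted p = 4.73e-05; adjusted p = 0.802 with an estimated correlation) and blood genes higher in 7 of 7 (mean 0.94, adjusted p = 4.73e-05; adjusted p = 0.564 with an estimated correlation). Immediate early genes (23 of 34 lower, mean −0.15, adjusted p = 8.85e-05) and microglia markers (14 of 16 lower, adjusted p = 0.0421) were lower, and genes of AMPA receptor auxiliary and scaffold proteins were higher (22 of 27, mean 0.15, adjusted p = 0.0421), with adjusted p of 0.564, 0.802 and 0.802 with an estimated correlation. The oligodendrocyte difference in the libraries' list means went from −0.36 to −0.10 without saline RFP replicate 3 (adjusted p = 0.449) and to −0.54 without replicate 2. That of microglia went from −0.19 to 0.02 without saline RFP replicate 2 (0.992), to −0.10 without replicate 4 (0.218) and to −0.44 without replicate 5. Microglia also failed to pass without heroin RFP replicate 3, 4, 9, 10, 12 or 13 or heroin SHISA7 replicate 13 (0.0504 to 0.166). The auxiliary proteins failed without any 1 of 11 libraries (0.0504 to 0.158). These were saline RFP replicates 2 to 4, heroin RFP replicates 2, 5 and 9 to 13, and heroin SHISA7 replicate 13. Oxidative phosphorylation genes turned from a mean of 0.11 to −0.20 when the 8 libraries with other titles were left out (adjusted p = 3.18e-21) and ribosomal protein genes from 0.13 to −0.16 (1.27e-16) with the preset correlation, each at an adjusted p = 0.548 with an estimated one. Among suffixed titles, with 4 heroin and 5 saline libraries, the immediate early list differed by 0.06 (exact permutation p = 0.484).

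Among SHISA7 rats, 390 genes differed between heroin and saline in edgeR, 367 higher and 23 lower in heroin, and 3012 had an unadjusted p under 0.05. Immediate early genes were higher in 30 of 34, with a mean of 0.69 (adjusted p = 3.42e-07; adjusted p = 0.147 with an estimated correlation), 7 past the test over all genes and 11 adjusted over the list alone. With an estimated correlation the list passed only without heroin RFP replicate 12 (adjusted p = 0.0475). Nr4a3 was at 8.99 ± 4.01 CPM (SD, n = 13) in heroin and 4.02 ± 0.793 CPM (SD, n = 7) in saline, a log2 difference of 1.16 (SE 0.223, adjusted p = 0.0362), and lay above the saline median in 13 of 13 libraries. Egr4 (2.45), Klf2 (2.30) and Ier5 (1.85) rose as well, as did the heat shock gene Hspa1b (1.55) and the chaperone Dnaja4 (1.23). Klf2 was at 0.134 to 0.675 CPM in saline SHISA7, where 1 read stood for 0.0375 to 0.0463 CPM. Large differences were also seen for Rn45s (3.61), Taf10 (3.35), C1qtnf4 (2.68), Cnih2 (2.63), Camk2n1 (2.37), Sema6b (2.37), Lrfn1 (2.29), Jund (2.25) and Epop (2.24). Without the 8 libraries with other titles edgeR called 0 genes, with 1484 at an unadjusted p under 0.05; Nr4a3 was then at 1.22 (adjusted p = 0.0700), Egr4 at 0.40, Klf2 at 1.00, Ier5 at 0.55, Hspa1b at 1.41, Dnaja4 at 0.23, Rn45s at −0.14 and Camk2n1 at −0.07, and the mean of the immediate early list was 0.48. All saline SHISA7 libraries had plain pairs, against 2 of the 13 in heroin, so the title form enters this comparison too. Among plain pairs alone the list mean was higher in heroin by 0.29 (2 against 7 libraries, exact permutation p = 0.111).

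Interferon-induced genes were lower in heroin among SHISA7 rats, in 22 of 26 (mean −0.43, adjusted p = 9.48e-04; adjusted p = 0.569 with an estimated correlation). None of the 26 passed over all genes and 1 passed adjusted over the list alone. Outside that list, the guanylate-binding protein Gbp2 (−2.03), the GTPases Ifi47 (−1.52) and Igtp (−1.27), which interferon also induces, MGC108823 (−1.27) and the chemokine Cxcl10 (−3.61) of the inflammation list fell. Gbp2 was at 3.46 ± 1.24 CPM (SD, n = 13) in heroin and 14.1 ± 22.2 CPM (SD, n = 7) in saline, where replicate 2 held 63.7 CPM and the other 6 libraries 2.71 to 13.8 CPM. Without saline SHISA7 replicate 2, Gbp2 was at −0.77, Ifi47 at −0.65, Igtp at −0.47 and Cxcl10 at −1.23, none past the test, and the interferon list had an adjusted p = 0.0903. Tspyl4 (−0.72), Lcmt2 (−0.65), Camk1g (−0.50) and Galnt18 (−0.46) were lower as well. Leaving out any 1 of the 7 saline SHISA7 libraries left 0 or 1 called gene in edgeR, with 2494 to 2847 at an unadjusted p under 0.05. Without replicate 2, Nr4a3 was at 1.20 and Taf10 at 3.37, each with an adjusted p = 0.0680. DESeq2 called 972 genes and limma-voom 1 over all libraries.

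Lists of neuronal genes were higher in heroin among SHISA7 rats with the preset correlation, in a comparison that shares its 13 heroin SHISA7 libraries with the one within heroin. Tbr1 (1.32), Slc17a7 (1.36) and Neurod2 (1.11) rose among excitatory neuron markers (10 of 15 higher, adjusted p = 0.0231; adjusted p = 0.569 with an estimated correlation), and Olig1 (1.62) and C1ql1 (2.30) among precursor markers, a list that did not pass (adjusted p = 0.0599). It passed with the preset correlation without any 1 of heroin SHISA7 replicates 4 to 7 and 9 or saline SHISA7 replicates 2 and 4 (0.0229 to 0.0443). Without saline SHISA7 replicate 2 its adjusted p was 0.693 with an estimated correlation. Potassium and sodium channel genes were higher in 22 of 28 (mean 0.46, adjusted p = 0.00907; adjusted p = 0.774 with an estimated correlation), with Hcn2 (2.95) and Kcnc1 (0.81) among those past the test, and genes of AMPA receptor auxiliary and scaffold proteins in 21 of 27 (mean 0.47, adjusted p = 0.00523; adjusted p = 0.569 with an estimated correlation), with Cnih2 and Homer1 (0.97). Grik5 (1.89), Grin2c (1.71), Slc12a2 (0.99), Slc12a5 (1.05), Lhfpl4 (0.83), Adrb1 (3.82), Adra2c (1.88), Drd2 (2.08) and Timp2 (1.12) rose from lists that did not pass. In saline SHISA7, Adrb1 was at 0.134 to 0.450, Drd2 at 0.0438 to 0.621 and C1ql1 at 0.0893 to 0.949 CPM. There 1 read stood for 0.0375 to 0.0463 CPM, so these 3 differences rest on few reads in saline. Ribosomal protein genes (72 of 73 higher, mean 0.32, adjusted p = 1.01e-04) and blood genes (7 of 7, mean 0.99, adjusted p = 0.00250) were higher, and microglia (13 of 16 lower, adjusted p = 0.0176) and astrocyte markers (12 of 15 lower, adjusted p = 0.0231) lower, with adjusted p of 0.774, 0.569, 0.641 and 0.569 with an estimated correlation. The excitatory (adjusted p = 0.571), channel (0.148), AMPA auxiliary (0.248), ribosomal (0.770) and astrocyte (0.0521) lists no longer passed with the preset correlation when the 8 libraries with other titles were left out. The mean of oligodendrocyte markers, a list that did not pass over all libraries, rose there from 0.60 to 0.89. The SE over libraries was 0.363, on the different scale of their list means of log2 CPM. On that scale heroin SHISA7 replicate 13 was at 8.67 and the other heroin SHISA7 libraries with pairs at 6.05 to 6.61. Saline SHISA7 libraries were at 5.60 to 6.53, so much of the rise rested on replicate 13. Without the 8 libraries Slc17a7 was at 0.32, Hcn2 at 0.26, Cnih2 at 0.30, Slc12a5 at 0.11 and Adrb1 at 0.41, none past the test. Without saline SHISA7 replicate 5 alone the excitatory (adjusted p = 0.0506) and microglia (0.0888) lists no longer passed. In the libraries' list means, the channel difference went from 0.26 to 0.17 without heroin SHISA7 replicate 10 and the ribosomal one from 0.21 to 0.11 without replicate 5.

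Whether the SHISA7 difference itself differed between heroin and saline was tested with the interaction. In edgeR 0 genes passed and 1041 had an unadjusted p under 0.05; DESeq2 called 2 and limma-voom 4. Nr4a3 came closest, with a difference of 1.58 (SE 0.318, adjusted p = 0.258). Fosb (1.23), Mctp1 (1.35), Itgbl1 (1.80) and Taf5 (1.34) had positive differences and Lcmt2 (−0.87), Atcay (−0.59), Pnma1 (−0.76), MGC95210 (−0.54) and Camk1g (−0.63) negative ones, all at an adjusted p = 0.871. Immediate early genes as a list had a mean difference of 0.84, positive in 31 of 34 (adjusted p = 1.75e-13; adjusted p = 0.00731 with an estimated correlation). When the 8 libraries with other titles were left out, the mean was 0.65. The SE over libraries was 0.170 (0.152 with all), on the different scale of their list means of log2 CPM. The list then passed with the preset correlation (adjusted p = 4.32e-14) but not with an estimated one (adjusted p = 0.121) or in fry (adjusted p = 0.0752), as the estimated correlation rose from 0.119 to 0.237. In saline the second label and the title form coincide, so this difference carries the title form as well.

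Across genes, the human heroin differences and the rat heroin differences with RFP correlated with r = 0.0928 over 10805 genes of equal symbol (permutation p = 0.42; Spearman's rho 0.0663, permutation p = 0.68), and 50.5% had the same sign against 49.2% with permuted labels. The SHISA7 differences in heroin and saline correlated with r = 0.183 over 18398 genes (permutation p = 0.089), and the heroin differences with RFP and SHISA7 with r = 0.176 (permutation p = 0.44). Genes are not independent replicates, so the p-values come from regrouping the libraries 100 times.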

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

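The lists and library values were screened by rules set before the data were examined, while the tests of explanations given here were chosen after the results had been seen, and for the SHISA7 label the condition for excluding it was made stricter after a first value had been seen. Whether the SHISA7 difference differed between heroin and saline was tested for 26 lists, and 7 passed with the preset correlation. Oligodendrocyte markers had the widest gap, a mean of 1.03 (adjusted p = 1.63e-05; adjusted p = 0.639 with an estimated correlation), with all 15 higher. Potassium and sodium channel genes (0.49, adjusted p = 0.00435) and ribosomal protein genes (0.19, adjusted p = 0.00966) were higher, with adjusted p of 0.776 and 0.889 with an estimated correlation. Astrocyte markers (−0.23, adjusted p = 0.00525), vascular markers (−0.29, adjusted p = 0.0188) and interferon-induced genes (−0.42, adjusted p = 0.0126) were lower, with adjusted p of 0.430, 0.560 and 0.70. The channel (adjusted p = 0.645) and interferon (0.0915) lists no longer passed with the preset correlation without the 8 libraries with other titles. Oxidative phosphorylation genes, not among the 7 lists, went from a mean of 0.04 to 0.20 there. The SE over libraries was 0.169, on the different scale of their list means of log2 CPM. In the libraries' list means the oligodendrocyte gap went from 0.67 to 0.41 without saline RFP replicate 3 (adjusted p = 0.0125) and to 0.48 without heroin SHISA7 replicate 13. The interferon gap went from −0.30 to −0.11 without saline SHISA7 replicate 2 (adjusted p = 0.396) or saline RFP replicate 5 (0.471). It did not pass either without saline SHISA7 replicate 5 or heroin RFP replicate 7 or 8 (0.0509 to 0.0804). Ribosomal protein genes no longer passed without heroin SHISA7 replicate 5 or 7, heroin RFP replicate 1 or 12, or saline SHISA7 replicate 4 (0.0590 to 0.447). Nor did vascular markers without saline SHISA7 replicate 5 (0.0501). The ribosomal gap went from 0.18 to 0.08 and 0.11 without heroin SHISA7 replicates 5 and 7 and to 0.28 without heroin RFP replicate 5.

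Immediate early genes had a mean of 0.84 in that test, with an adjusted p = 0.00731 with an estimated correlation, and were lower with SHISA7 in saline. Without the 8 libraries the means were 0.65 and −0.49 (from 0.84 and −0.49), and both passed with the preset correlation (adjusted p of 4.32e-14 and 1.75e-11) but not with an estimated one (0.121 and 0.251). A library batch that follows the title form is a candidate explanation for the saline difference: within heroin RFP, where the second label is constant, libraries with plain pairs lay below those with suffixed pairs by −0.46 (exact permutation p = 0.0121), close to the −0.51 in saline (exact permutation p = 0.00126, 7 against 5 libraries). Of these plain pairs heroin RFP replicate 12 was lowest, at 3.72, and the rest were at 4.32 to 4.59. The second label is constant within heroin SHISA7 too, and the gap was smaller there. Plain pairs were at 4.50 ± 0.0533 (SD, n = 2) and suffixed pairs at 4.69 ± 0.325 (SD, n = 5). Within suffixed titles, heroin SHISA7 and heroin RFP differed by −0.0940 (SE 0.167, exact permutation p = 0.603), which leaves the SHISA7 label open, since heroin is present there and 5 and 4 libraries bound it loosely. Title form and second label coincide in saline and cannot be told apart there.

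Among 134 groups of values tested for a single library apart from its group, 6 had one, about as many as chance gives, since it marks about 1 in 20 groups. Among these 6, saline SHISA7 replicate 2 had the highest total count, 26.7 M, with the nearest library at 23.6 M. Nr4a2 was lowest in saline SHISA7 replicate 1, at 3.57 log2 CPM against 4.49 in the nearest, and Drd2 in saline SHISA7 replicate 7, at −2.97 against −1.51. Jund was highest in saline RFP replicate 2, at 2.00 log2 CPM against 1.12, and Timp2 in saline RFP replicate 4, at 5.71 against 5.26.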

How the results depend on the processing

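The settings that left out the 8 libraries with other titles, any library outside saline RFP, any library in the list tests, or single SHISA7 rows, and the test of single transcript rows, were chosen after the data had been seen. The human SHISA7 difference stayed past the threshold under every planned setting, from −1.32 to −1.60, and ended at −0.00880 with the class 0 row alone and −0.13 without row P12080. The human count of 110 rose to 267 with surrogate variables, 376 with the first principal component, 307 with cell type means and 459 with robust moderation and weights, and was 34 over single transcript rows; the cause was not tested. For SHISA7 minus RFP in heroin edgeR called 0 genes with the title form as a covariate, with only the 2 groups compared, within each title form and without the 8 libraries, and limma-voom called 0, with 4935, 2410, 654 (suffixed), 1687 (plain), 3145 (other), 1086 and 2706 at an unadjusted p under 0.05. Shisa7 there was 0.52 with limma-voom (adjusted p = 0.201), 0.80 with the title form (adjusted p = 0.108), 0.68 with only 2 groups (adjusted p = 0.0885), 0.42, 0.77 and 1.39 within suffixed, plain and other titles and 0.53 without the 8 libraries, none past the threshold. Fewer libraries entered the within-form settings. Among other titles, 4 of the 6 SHISA7 libraries lay in a set without an RFP library, so the 1.39 compares in part unlike sets. Leaving out 1 library at a time gave 0 to 1489 genes and a Shisa7 difference of 0.60 to 0.75. The count was 0 without heroin SHISA7 replicate 2, 3 or 10, where Shisa7 had adjusted p of 0.0595, 0.0632 and 0.0766, 1489, 1319 and 1237 without replicates 7, 8 and 9, and 1244 without heroin RFP replicate 12.

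For SHISA7 minus RFP in saline DESeq2 called 3 genes, limma-voom 9 and the 2-group model 3, and single omissions gave 0 to 1, with 1 without heroin RFP replicate 8 or heroin SHISA7 replicate 8. For heroin minus saline with RFP, DESeq2, the title form covariate, the 2-group model, suffixed titles alone and the setting without the 8 libraries gave 0 genes, with 393, 370, 243, 994 and 531 at an unadjusted p under 0.05, and limma-voom gave 3. Single omissions gave 0 to 2: 0 without saline RFP replicate 1, saline SHISA7 replicate 3, heroin RFP replicate 2 or heroin SHISA7 replicate 12, and 2 without heroin RFP replicate 8. Shisa7 in this comparison turned from −0.07 to 0.0173 among suffixed titles and to 0.0291 without the 8 libraries, all within its interval. For heroin minus saline with SHISA7 DESeq2 called 972 genes, limma-voom 1, edgeR without a count filter 148 and with the title form 1. Only 2 groups, plain titles alone and leaving out the 8 libraries gave 0, with 2347, 3102 and 1484 at an unadjusted p under 0.05. Single omissions gave 0 to 841: 0 or 1 without any saline SHISA7 library, 116, 223, 224, 240 and 247 without saline RFP replicates 1 to 5, 237 and 259 without heroin RFP replicates 2 and 3, 0, 2 and 0 without heroin SHISA7 replicates 2, 3 and 10, and 728, 672, 597, 841 and 744 without replicates 4, 6, 7, 8 and 9. For the interaction DESeq2 called 2, limma-voom 4 and the title form covariate 1, and single omissions 0. Without the 8 libraries Rn45s turned to −0.0234, Camk2n1 to −0.0529 and Adrb1 to −0.29 for SHISA7 minus RFP in heroin, and Rn45s to −0.14 and Camk2n1 to −0.0703 for heroin minus saline with SHISA7.

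The number of lists past the threshold with the preset correlation, an estimated correlation and fry was 11, 0 and 1 in the human data, 15, 0 and 6 for SHISA7 minus RFP in heroin, 6, 1 and 0 in saline, 5, 0 and 0 for heroin minus saline with RFP (9 without the 8 libraries), 9, 0 and 1 with SHISA7, and 7, 1 and 1 for the interaction. Leaving out any 1 rat library gave 12 to 15, 5 to 9, 3 to 6, 8 to 12 and 5 to 10 lists with the preset correlation, in the same order. With the 8 libraries left out, the immediate early list passed with the preset correlation in saline and the interaction, and had an adjusted p = 0.251 and 0.121 with an estimated one. With the title form as a covariate the correlations across genes of the SHISA7 differences and of the heroin differences turned to −0.39 (permutation p = 0.0099, the smallest it can give) and −0.39 (permutation p = 0.03). In saline the form and the second label coincide, so in this model the form effects are estimated from heroin libraries alone. Their error enters both correlated differences with opposite sign, which can give a negative correlation by itself. Regrouping broke the tie between form and label, so these p-values do not cover that error and nothing is concluded from them. No paired analysis was possible because replicate numbers were given in accession order.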

Other observations

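All tests of explanations given here were chosen after the results had been seen, except the comparisons with other splits of the libraries. For the factor per library shared with short RNA genes and for the SHISA7 label in heroin, the condition was made stricter after a first value had been seen, and the test of abundant genes replaced an earlier one. Some of the 77 human genes lower in heroin are known from endothelial cells; they were picked by hand after their values were seen, and the fixed vascular list had an adjusted p = 0.640 with an estimated correlation. CD34, a surface protein of endothelial and haematopoietic precursor cells, was at 4.36 ± 2.08 FPKM (SD, n = 34) in heroin and 6.58 ± 1.99 FPKM (SD, n = 28) in control, a log2 difference of −0.65 (SE 0.148; limma, adjusted p = 0.0112). The phospholipid flippase gene ATP10A (−0.49, adjusted p = 9.51e-05), the lipoprotein receptor gene LSR of tight junctions (−0.63, adjusted p = 0.00302), the TGF-beta receptor genes TGFBR2 (−0.47) and ENG (−0.42), the endothelial transcription factor genes FLI1 (−0.41) and SOX17 (−0.37), the receptor gene TIE1 (−0.37), the phosphatase gene PTPRB (−0.42), NOSTRIN (−0.43), which binds nitric oxide synthase, the amino acid transporter gene SLC7A5 (−0.41) and A2M (−0.61), a protease inhibitor, fell too. The GTPase genes GIMAP7 (−0.67), GIMAP6 (−0.46) and GIMAP4 (−0.38) fell alongside. In the rat, Nostrin (−0.54) and Edn1 (−0.66) were lower with SHISA7 in heroin, a contrast of the second label and not of heroin. Neither passed without the 8 libraries with other titles (−0.49 and −0.52, edgeR, each at an adjusted p = 0.817). For heroin minus saline with RFP, the rat vascular list had a mean of 0.21, the opposite direction to the human one, and did not pass. The SE over libraries was 0.0895, on the different scale of their list means of log2 CPM.

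Lists that passed in no comparison over all libraries were those of opioid signalling (adjusted p 0.465 to 0.938), monoamine receptors (0.531 to 0.916), extracellular matrix and perineuronal nets (0.404 to 0.905), striatal neurons (0.306 to 0.996) and, in the rat alone, olfactory neurons (0.251 to 0.971). Without the 8 libraries with other titles, striatal neurons passed with the preset correlation for SHISA7 minus RFP in heroin (adjusted p = 0.0283) and for heroin minus saline with SHISA7 (0.0231), and not with an estimated one (0.357 and 0.682). Mitochondrially encoded genes had too few members to test.

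The 785 genes for SHISA7 minus RFP in heroin were weighed against the title form. Of 60 splits of the libraries, 3 gave as many genes, the real one included, and the highest other gave 6299, so chance was not excluded, and that split points to a structure of the samples. A few abundant genes as the cause are argued against, because the 10 most abundant took 3.71 to 9.39% of counts, which could shift the remaining genes by at most 0.0878 between any 2 heroin libraries, against a median of 0.86 for the 751 higher genes. The SHISA7 label stays open: the median was 0.25 within suffixed titles (SE 0.169 for the libraries' mean over these genes), 0.50 within plain pairs (SE 0.171) and 1.26 within other titles (SE 0.446), and genes chosen over all libraries lose part of their size in subsets. A batch stays open too, as the median was 0.26 without the 8 libraries. The rise lay in replicates 2, 3, 10 and 12, all SHISA7, and not in the other 4 with other titles. The label is the same in all heroin SHISA7 libraries. By itself it does not account for the gap of 1.40 between replicates 2, 3, 10 and 12 and SHISA7 libraries with pairs. Without these replicates the median for SHISA7 minus RFP in mean log2 CPM was 0.22. In the difference over all libraries, the label and a batch of replicates 2, 3, 10 and 12 cannot be told apart. Of these, replicates 2, 10 and 12 have a suffix in the title, while replicate 3 has a bare number like the other set. The sets were split on the same expression values, so the gap between them is no test. No RFP library lies in the set with the rise, so the 1.26 within other titles compares in part unlike sets.

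The fall of SHISA7 row P12080 and of short RNA genes in the human heroin group was weighed next. Chance is argued against for the 110 genes: 1 of 100 splits, the real one, gave as many, and the highest other gave 1. That is the smallest share 100 splits can give. Such splits assume independent libraries, which the labels do not state. A shift of reads to the other SHISA7 rows is argued against, since their summed FPKM changed by −0.144 (SE 0.301) while P12080 lost −7.55. A factor per library shared with short RNA genes stays open: within control libraries P12080 correlated with their score with r = −0.42 (permutation p = 0.027, adjusted p = 0.054; rho = −0.28, p = 0.147; r = −0.33 without the 2 farthest libraries), and within heroin with r = 0.23 (permutation p = 0.179; rho = 0.22, p = 0.202; r = 0.16 without the 2 farthest). A preparation or quantification that differed between the groups is likewise a candidate source, since 29.4% of short RNA genes passed and no batch is given in the labels, so it cannot be told apart from heroin use, which remains open as well.

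Splits of the rat libraries were also counted for the remaining contrasts. For SHISA7 minus RFP in saline and for the interaction, the real count in edgeR was 0, so all 60 of 60 splits gave as many by necessity and the count says nothing about chance; the highest others were 1 and 5. For heroin minus saline with RFP the real count was 1 and 5 of 60 splits, the real one included, gave as many, with the highest other at 2, so chance was not excluded. For heroin minus saline with SHISA7, 2 of 60 splits, the real one included, gave at least the 390 genes. That share is under 0.05, but the other of these 2 splits gave 502.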
